A study of Mus musculus with 10 samples.

How the data were processed

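Total RNA from the livers of 10 mice aged 28 days was amplified, labelled with biotin and hybridised to Affymetrix mouse expression arrays, per the labels' protocols and the form of the probe set names. The animals had been fasted for 5 hours, and RNA had been isolated with a kit that retains small RNA, per the labels' protocols. Of the arrays, 5 came from control mice and 5 from mice that carried floxed alleles of Dicer1 on both chromosomes and a Cre recombinase under the control of the Afp gene, which is active in the fetal liver. Group and replicate number came from the sample titles. The labels give the strain only as mixed. They give no sex, litter or processing batch, and scan dates were not used here, so no batch could be tested.

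The authors deposited 1 table of log2 values per probe set, made comparable between arrays before deposit. The scale was read from the values, which run from 0.27 to 16.7 with near-equal distributions on all arrays. The log base, background correction, summary method and normalization are not given in the sources used here, and a linear difference computed from these values depends on them. The array medians lie between 6.41 and 6.68. The 25th percentile of all values is 3.60 and is called the floor here. It is a convention and not a measured detection limit, since values run down to 0.27. A difference against a group mean in that range depends on how the authors treated background. Detection calls were not used here. Precision is limited by the number of arrays, 5 in each group.

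The table holds 25995 probe sets. After 37 control probe sets were left out, 21613 carried 1 gene symbol, 638 carried several and 3707 carried none in the platform annotation used here. Symbols were checked against a table of mouse genes on assembly GRCm38.p6 through their gene identifiers. The check changed 0 symbols, and 61 identifiers had no match and kept their symbol. That table also gave the genomic span of genes for 1 check, with a value for 99.8% of genes. No coordinates are given, since the array files name no genome build. Each gene was represented by the probe set with the highest mean over the 10 arrays, which gave 12366 genes. Probe sets with several symbols or none were tested but not named.

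Differences between mutant and control were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all genes, and were called at an adjusted p under 0.05. Every adjusted p for a gene in the text comes from this model unless another test is named. Differences are mutant minus control on the log2 scale, with the moderated standard error. The replicate numbers are the same in both groups, but the labels say nothing of shared litters, and the model had no block. For the Dicer1 probe sets the adjustment ran over all probe sets.

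Before the data were examined, 29 gene lists were fixed, covering microRNA targets, the microRNA machinery, hepatocyte functions, stress responses and markers of the other cell types of the liver. Each list was tested against all other genes with camera of limma at a preset correlation between genes of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 29 lists. Camera with an estimated correlation and the directional test fry, which asks whether the genes of a list move one way and does not compare them with other genes, were run beside it. Members past the gene test were counted after adjustment over all genes and again adjusted over the list alone. A planned comparison of genes with and without microRNA seed sites was not run, since 3 prime untranslated sequences were not used here.

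Genes named in the text followed a rule fixed at the same time. It took Dicer1 and, in each direction, the 12 genes with the largest differences among those called, with groups that did not overlap, a higher group mean at or above the median of all genes (7.63), and no clone or predicted name. It also took up to 4 members of each list with the smallest p, or up to 6 for the miR-122, fetal and imprinted lists. Members of lists that camera did not call could be left out. Genes of near-identical families, here Cyp3a16, Cyp2b9, Cyp2b13 and Acot3, can share probe signal with their relatives and are uncertain in identity.

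The gene test was tested on simulated data for the 12366 genes, with the spread of the real arrays and 200 changed genes. It recovered 17 of 50 genes changed by 0.5 on the log2 scale, 34 of 50 changed by 1, 47 of 50 changed by 2 and 48 of 50 changed by 3. Of the 154 genes it called, 8 were unchanged ones. The simulated noise was normal and independent between genes, with 1 SD per gene for both groups. Real genes are correlated and can differ in spread between groups, so these rates need not hold for the real arrays.

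The alternatives were quantile normalization, subtraction of the array median or 75th percentile, a filter on dim genes, other rules for the probe set of a gene, eBayes with trend and robust options, array weights, the replicate number as a block, leaving out each array in turn, testing every probe set on its own, counting genes whose groups do not overlap, and lists without shared members. Pseudocounts did not apply to values already on a log scale. The Xist signal as a covariate was added after the data were seen.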

Results

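The livers of 5 control mice and 5 mice with a liver deletion of Dicer1 were compared at 28 days of age, with 1 array for each animal. The comparison asks which liver transcripts differ when the enzyme that makes mature microRNAs is lost. Its p-values measure the spread between these livers. Pairs of arrays correlated between 0.970 and 0.993 over all probe sets, and 0 pairs were identical. Component 1 of a principal component analysis held 50.4% of the variance between arrays. The controls lay between -31.8 and -21.0 on it, 4 mutants lay between 23.5 and 47.3, and mutant replicate 5 lay at -9.50. Probe sets for Xist and for genes of the Y chromosome separated each group into 3 arrays with Y-linked signal and 2 with high Xist signal. Control replicate 4 and mutant replicate 3, counted with Y-linked signal, also had some Xist signal on 2 of 3 probe sets. They stood at 6.72 and 7.21 on 1 of these and at 5.88 and 6.09 on the other. The other arrays with Y-linked signal ran from 2.65 to 3.99 and from 1.49 to 2.46 on these probe sets. On the remaining Xist probe set the 2 arrays stood at 3.10 and 2.97, against 2.73 to 2.94.

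Dicer1 was lower in all 5 mutant livers on both of its probe sets. The first averaged 8.06 ± 0.04 (SD, n = 5) in controls and 5.75 ± 0.23 (SD, n = 5) in mutants, a difference of -2.31 (SE 0.10, adjusted p = 4.1e-05). The other averaged 8.08 ± 0.10 (SD, n = 5) and 7.06 ± 0.10 (SD, n = 5), a difference of -1.03 (SE 0.07, adjusted p = 0.000678). Mutant replicate 5, at 5.84 and 6.98, was as low as the other mutants on both. Where the probe sets lie relative to the deleted exons is not given in the sources used here, and a probe set outside them would not report recombination.

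Other genes of the microRNA machinery rose while Dicer1 fell. Of 14 measured members, 7 were higher and 1, Dicer1 itself, was lower, with the same 7 and 1 adjusted over the list alone. Tnrc6a and Tnrc6b, which encode scaffold proteins of the silencing complex, rose by 1.22 (SE 0.17, adjusted p = 0.00601) and 0.88 (SE 0.11, adjusted p = 0.00429), with probe sets from 0.80 to 1.46 and from 0.37 to 0.88. Mov10, an RNA helicase, rose by 1.05 (SE 0.18, adjusted p = 0.00853) on 1 of its 2 probe sets, while the other did not rise. The median difference of the list was 0.26, with an adjusted p of 0.0296 by camera and an adjusted p = 0.348 with an estimated correlation. Its call was also lost without control replicate 2 (adjusted p = 0.0505), control replicate 3 (0.0520), mutant replicate 3 (0.0664) or dim genes (0.0643), within 0.00386 to 0.0664 over the other settings of camera.

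**Figure D1:**
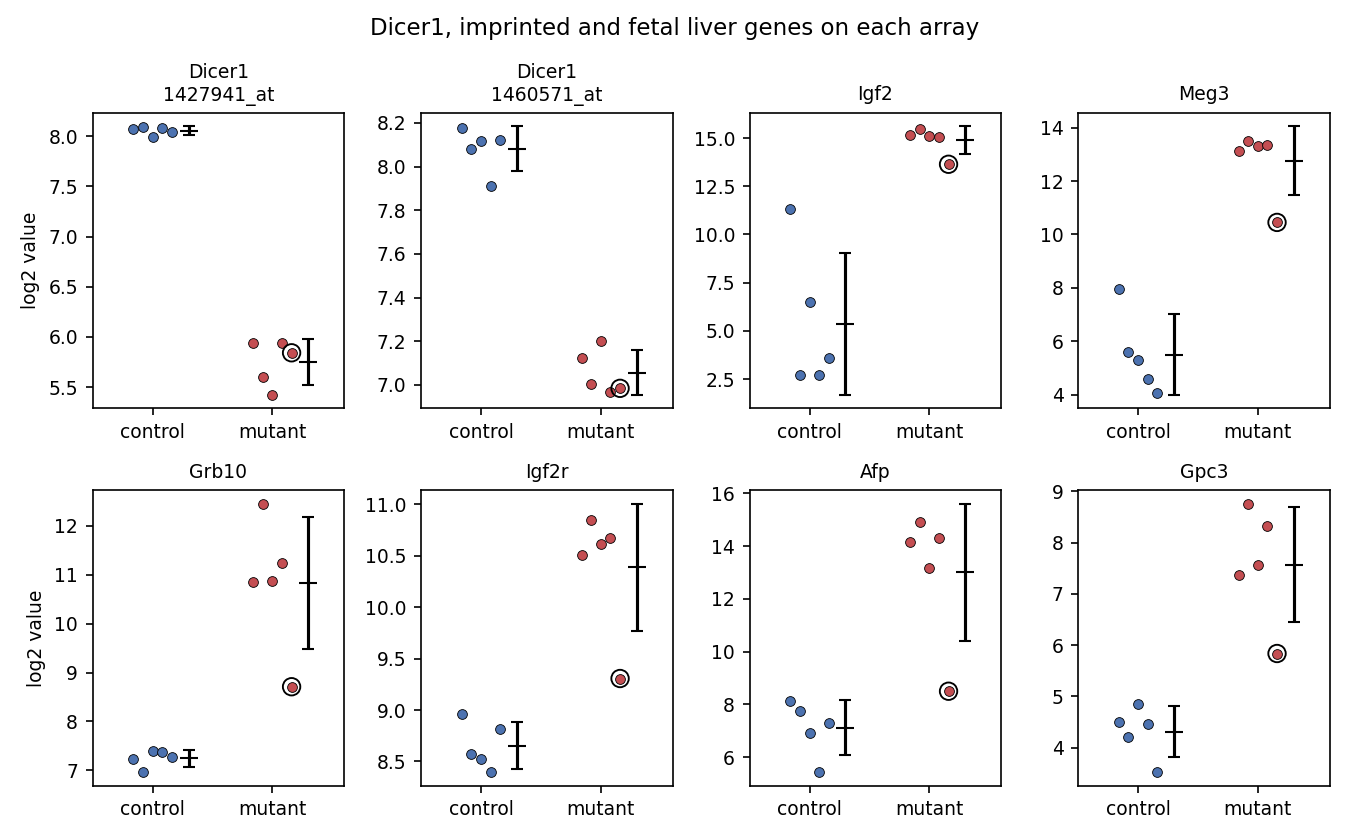
Deposited log2 values of 2 Dicer1 probe sets, 4 imprinted genes and 2 fetal liver genes on each array, with points for single livers and a bar for the mean ± SD of the 5 livers beside them. The ringed point is mutant replicate 5, which has Dicer1 values of 5.84 and 6.98 like the other mutants but Afp at 8.50, near the controls.

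Of 12366 genes, 1066 were higher and 1422 were lower in mutant liver. Differences of at least 1 on the log2 scale were seen for 202 of the higher and 187 of the lower genes. Among genes with groups that did not overlap, a higher mean at or above the median of all genes (7.63) and no clone or predicted name, the largest increases included Igf2, the fetal growth factor, at 9.52 (SE 1.54, adjusted p = 0.00742), the imprinted noncoding RNAs Meg3 at 7.26 (SE 0.82, adjusted p = 0.00308) and Rian at 4.80 (SE 1.06, adjusted p = 0.0168), and Afp, the fetal serum protein, at 5.90 (SE 1.15, adjusted p = 0.0115). Igf2 varied among controls, from 2.69 to 6.52 on 4 arrays and 11.34 on control replicate 1, without which the difference was 11.01. Signal lay below the floor of 3.60 on 3 control arrays for Igf2, on 2 for Rian and Cyp3a16 and on 1 for Prom1, Acot3, Ntrk2 and Gpc3, so the size and order of these differences depend on how background was treated. The probe sets of these genes ran from 3.74 to 9.52 for Igf2, 1.35 to 7.30 for Meg3, 1.87 to 4.80 for Rian and 5.18 to 7.65 for Afp. Next within this selection were Prom1, a surface protein of progenitor cells (4.03), the cytochrome P450 Cyp3a16 (3.98), Lcn2, a lipocalin of the acute phase (3.89), the acyl-CoA thioesterase Acot3 (3.72), the imprinted adaptor protein Grb10 (3.58, and 1.36 on its other probe set), the actin-bundling protein Pls1 (3.30), the secreted matrix protein Smoc2 (3.12) and the neurotrophin receptor Ntrk2 (2.99). Of the 4 probe sets of Ntrk2, 1 differed by -0.02, and its call was lost without control replicate 1 or 2 or mutant replicate 1, 2, 3 or 4 (adjusted p from 0.0540 to 0.0737).

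Among the genes that fell in the same selection, Hsd3b5, a steroid dehydrogenase, fell by 3.93 (SE 0.75, adjusted p = 0.0114), Elovl3, a fatty acid elongase, fell by 3.46 (SE 0.87, adjusted p = 0.0253), and Slco1a1, an organic anion transporter, fell by 2.89 (SE 0.68, adjusted p = 0.0200). The largest decrease in this selection was that of Rad51b, a recombination protein, at -4.13 (SE 0.61, adjusted p = 0.00645), where 1 mutant array lay below the floor, as for Elovl3. The rest of this selection were Nlrp12 (-4.06), the dehydrogenase Sdr9c7 (-3.60), the ion channel Asic5 (-3.46), the G protein regulator Rgs16 (-2.56), the glycosyltransferase Ugt3a1 (-2.37), the mitochondrial adenylate kinase Ak4 (-2.27), complement C9 (-2.10) and the phosphatase Ppm1m (-2.09). The Elovl3 call was lost without control replicate 1, 4 or 5 or mutant replicate 4 (adjusted p from 0.0523 to 0.0602). Groups did not overlap for 1628 genes in all, against 98.1 (0.794%) that chance gives.

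Mutant replicate 5 changed less than the other mutants. Over the 668 genes called without it with a difference of at least 1, it reached a median share of 0.274 of the mean change of the other 4 mutants. Without it, 1371 genes were higher and 2160 lower, of which 300 and 368 differed by at least 1. Without mutant replicate 4 the counts were 627 and 764 (129 and 121 by at least 1), and without mutant replicate 2 they were 696 and 824 (147 and 104). The count of lower genes was 847 without mutant replicate 1, 930 without mutant replicate 3, and 782, 856 and 930 without control replicates 3, 4 and 5.

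**Figure D2:**
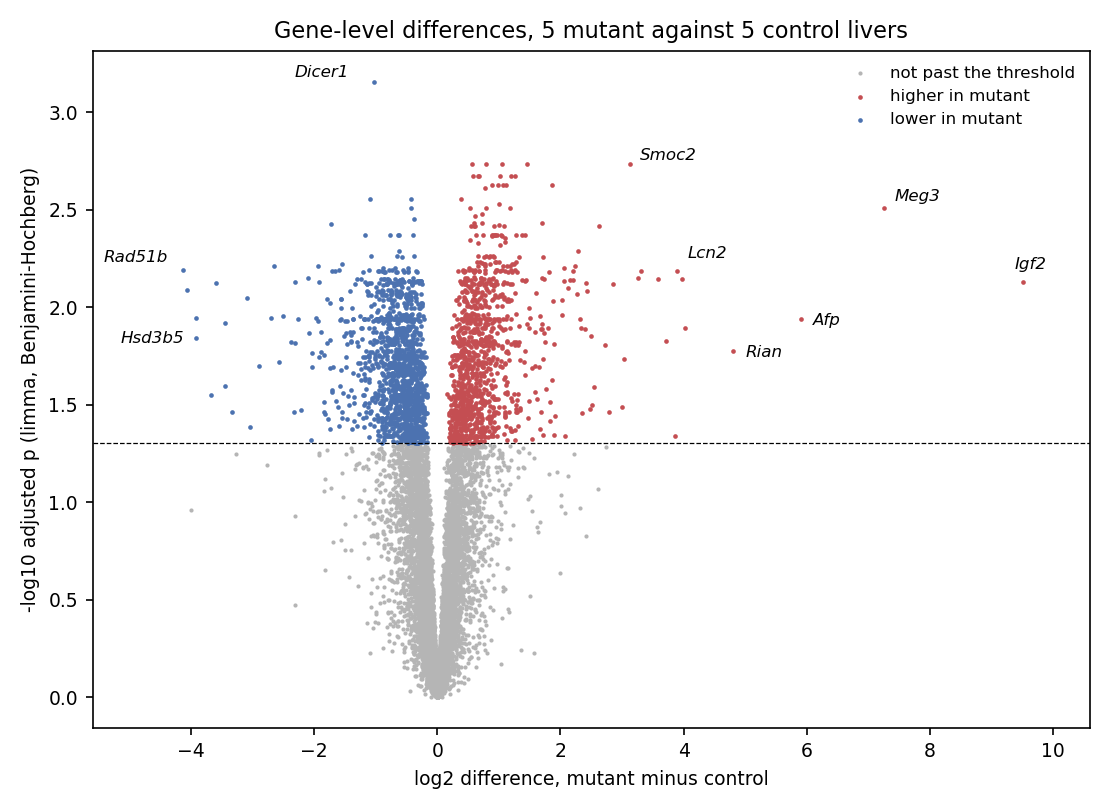
Difference of each of 12366 genes between 5 mutant and 5 control livers on the log2 scale (x axis) against -log10 of its adjusted p (y axis), with the dashed line at the threshold of 0.05. The 1066 genes higher in mutants are red and the 1422 lower ones blue, and Igf2 lies farthest to the right at 9.52.

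**Figure D3:**
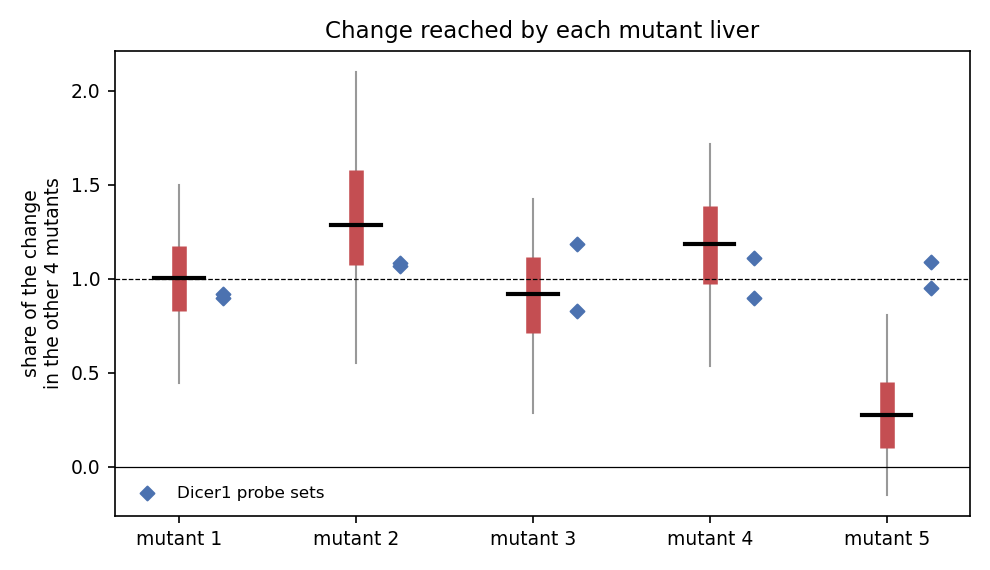
Share of the mean change of the other 4 mutants that each mutant liver reached, over genes called without that liver with a difference of at least 1, with the median (black bar), quartiles (thick bar), 5th to 95th percentile (thin line) and the 2 Dicer1 probe sets (diamonds). Mutant replicate 5 has a median of 0.274 over 668 genes, and the other mutants have medians from 0.916 to 1.28, against means that include mutant replicate 5.

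Targets of miR-122, the most abundant microRNA of hepatocytes, were higher in mutants as a group. Of 29 measured members, 18 rose, 1 fell and 10 did not pass the test, and 21 rose and 2 fell adjusted over the list alone. The glutathione peroxidase Gpx7 rose by 2.28 (SE 0.30, adjusted p = 0.00517), the ceramide synthase Cers6 by 1.38 (SE 0.22, adjusted p = 0.00724) and the membrane protease Adam10 by 1.06 (SE 0.15, adjusted p = 0.00617). The kinase Bckdk, the chloride channel protein Clic4 and the microtubule-binding protein Mapre1 rose by 0.95, 0.94 and 0.73, and the 4 probe sets of Mapre1 ranged from 0.06 to 0.73. The median was 0.68, with an adjusted p of 4.36e-09 by camera, an adjusted p = 0.234 with an estimated correlation and 4.06e-10 to 2.25e-06 under its other settings, and an adjusted p of 0.00203 by fry. The 1 that fell did so in the full set and without mutant replicate 5, but not without any other array.

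Of 12 measured let-7 targets, 5 rose and 0 fell, with the same counts adjusted over the list alone. They included the cell cycle gene Ccnd1 at 1.73 (SE 0.36, adjusted p = 0.0136), Myc at 1.86 (SE 0.46, adjusted p = 0.0237), Nras at 0.68 (SE 0.07, adjusted p = 0.00212) and the zinc finger gene Plagl2 at 1.07 (SE 0.22, adjusted p = 0.0131). Nras and Plagl2 each had 1 of 3 probe sets that did not rise. The Myc call was lost without control replicate 2 or 3 or mutant replicate 1 or 2 (adjusted p from 0.0507 to 0.0566), where 3 members of the list rose. The median was 0.52, with an adjusted p of 0.000103 by camera, an adjusted p = 0.234 with an estimated correlation and 4.9e-05 to 0.0189 under its other settings, and an adjusted p of 0.00198 by fry.

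Genes of the fetal liver that are silenced after birth were higher in mutants. Of 13 measured, 6 rose and 0 fell, and 7 rose adjusted over the list alone. Beside Afp and Igf2, the surface proteoglycan Gpc3 rose by 3.25 (SE 0.50, adjusted p = 0.00705), the transcription factor Sox4 by 1.28 (SE 0.36, adjusted p = 0.0345), the lipoprotein lipase Lpl by 0.76 (SE 0.23, adjusted p = 0.0484) and the tetraspanin Tspan8 by 1.12 (SE 0.16, adjusted p = 0.00617). The Tspan8 control mean, 3.56, lies just below the floor of 3.60, and 1 of its 3 probe sets did not rise. The Sox4 call was held only without mutant replicate 3 or 5 (adjusted p up to 0.0772 in the other 8 fits without 1 array), and the Lpl call only without control replicate 5 (up to 0.105 in the other 9). For the list the median was 0.76, with an adjusted p of 6.43e-05 by camera, an adjusted p = 0.234 with an estimated correlation and 3.57e-05 to 0.0135 under its other settings, and an adjusted p of 0.00138 by fry.

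Imprinted growth genes, which are expressed from 1 parental allele, were higher. Of 15 measured, 8 rose and 1 fell, with the same counts adjusted over the list alone. In addition to Igf2, Meg3 and Grb10, the cell cycle inhibitor Cdkn1c rose by 2.24 (SE 0.32, adjusted p = 0.00617) and Igf2r, the receptor that clears IGF2, rose by 1.73 (SE 0.27, adjusted p = 0.00718). Gnas fell by 0.31 (SE 0.05, adjusted p = 0.00733) on 1 probe set, and its other probe set differed by 0.20. The median was 0.45, with an adjusted p of 5.68e-05 by camera, an adjusted p = 0.348 with an estimated correlation and 7.35e-06 to 0.000749 under its other settings, and an adjusted p of 0.0102 by fry. Mutant replicate 5 had the lowest mutant value of Igf2, Meg3, Grb10, Cdkn1c, Igf2r, Afp and Gpc3, and without it Afp differed by 7.03.

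Differences of the main secreted products of hepatocytes were small on these arrays. Of 20 measured, 0 rose and 1, Ambp, fell (-0.16), 0 and 0 passed adjusted over the list alone, and 3 had an unadjusted p under 0.05 by limma. The differences ran from -0.33 to 0.12 with a median of -0.05 (camera adjusted p = 0.420). Control means reached 16.44, close to the highest value of all arrays, 16.65, where differences can be compressed. The number that fell was 0 without control replicate 1, 2, 3 or 4 or mutant replicate 1, 2 or 3 and 2 without control replicate 5, and without mutant replicate 5 it was 2, with 2 that rose. The albumin transcript Alb averaged 16.20 ± 0.11 (SD, n = 5) in controls and 16.24 ± 0.12 (SD, n = 5) in mutants.

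Fatty acid synthesis genes were lower. Of 14 measured, 5 fell and 0 rose, and 8 fell adjusted over the list alone. Scd1, the stearoyl-CoA desaturase, fell by 1.58 (SE 0.31, adjusted p = 0.0116), the malic enzyme Me1 fell by 1.34 (SE 0.22, adjusted p = 0.00764, with -0.69 on its other probe set), the acetyl-CoA carboxylase Acacb fell by 1.13 (SE 0.20, adjusted p = 0.00869) and the elongase Elovl5 fell by 0.33 (SE 0.10, adjusted p = 0.0441). The Elovl5 call held only without control replicate 1 or mutant replicate 5 (adjusted p up to 0.0979 in the other 8 fits without 1 array), and 3 members fell without control replicate 2, 3, 4 or 5 or mutant replicate 1, 2 or 4. The median was -0.53, with an adjusted p of 0.00507 by camera, an adjusted p = 0.367 with an estimated correlation and 0.000932 to 0.0504 under its other settings, the highest with dim genes left out, and an adjusted p of 0.0221 by fry.

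Of 11 measured pericentral hepatocyte genes, 3 rose and 0 fell, with the same counts adjusted over the list alone. They were Cyp1a2, a cytochrome P450, at 0.72 (SE 0.11, adjusted p = 0.00705), the ornithine aminotransferase Oat at 0.83 (SE 0.20, adjusted p = 0.0236) and the glutamate transporter Slc1a2 at 1.24 (SE 0.27, adjusted p = 0.0150), for which 1 of 3 probe sets differed by -0.39. The ammonium transporter Rhbg, at 0.47 (SE 0.24, adjusted p = 0.195), did not pass. The median was 0.27, with an adjusted p of 0.0109 by camera, an adjusted p = 0.397 with an estimated correlation and 0.00132 to 0.0430 under its other settings, and an adjusted p of 0.0620 by fry. Relative to the mean of all controls, the list mean ran from -0.26 to 0.32 in controls. Mutant replicates 2 and 4, at 0.17 and 0.02, lay within that range, and mutant replicates 1, 3 and 5, at 0.41, 0.66 and 0.56, lay above it.

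Genes with sex-biased expression in adult liver moved apart. Of 9 measured female-biased genes, 4 rose and 0 fell, and 5 rose adjusted over the list alone. They were Acot3, the steroid hydroxylase Cyp17a1 at 1.82 (SE 0.28, adjusted p = 0.00657), and the cytochromes P450 Cyp2b13 at 3.87 (SE 1.17, adjusted p = 0.0457) and Cyp2b9 at 1.71 (SE 0.52, adjusted p = 0.0453). Sult3a1 (-0.45), Hao2 (-0.47) and Abcd2 (-0.06) had differences of the other sign and did not pass. Of 9 male-biased genes, 4 fell and 0 rose, and 5 fell adjusted over the list alone. These were Hsd3b5, Elovl3, Slco1a1 and the cytochrome P450 Cyp2u1, which fell by 1.36 (SE 0.36, adjusted p = 0.0309) on 1 of its 2 probe sets. The medians were 1.15 and -1.36, with adjusted p of 0.0125 and 0.00470 by camera, an adjusted p = 0.367 and 0.348 with an estimated correlation, and 0.00104 to 0.257 and 0.000734 to 0.0890 under its other settings, the highest with dim genes left out. By fry the adjusted p were 0.0667 and 0.0193. The female-biased call was also lost without mutant replicate 5 (adjusted p = 0.0664). Only 2 female-biased genes rose without any 1 array other than control replicates 2 and 3, and 2 male-biased genes fell without control replicate 1 or 4 or mutant replicate 4. Calls held only without control replicate 2 for Cyp2b13, control replicate 2 or 3 for Cyp2b9, and mutant replicate 3 or 5 for Cyp2u1 (adjusted p up to 0.0951, 0.0931 and 0.0699 otherwise).

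Markers of Kupffer cells and macrophages were higher. Of 15 measured, 10 rose and 0 fell, and 12 rose adjusted over the list alone, among them the lysozyme Lyz2 at 1.05 (SE 0.23), the complement gene C1qa at 0.72 (SE 0.17), the growth factor receptor Csf1r at 0.62 (SE 0.16) and the lectin Clec4f at 0.59 (SE 0.13). The median was 0.59, with an adjusted p of 8.22e-06 by camera, an adjusted p = 0.348 with an estimated correlation and 1.04e-06 to 5.17e-05 under its other settings, and an adjusted p of 0.0221 by fry. The number that rose was 3 without control replicate 1 or mutant replicate 1 or 2, 4 without control replicate 5 or mutant replicate 4, 5 without control replicate 4 and 6 without control replicate 3. The Csf1r call was lost without control replicate 1 or mutant replicate 1, 2 or 4 (adjusted p from 0.0504 to 0.0590).

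Stellate cell and matrix genes were also higher. Of 17 measured, 8 rose and 0 fell, and 10 rose adjusted over the list alone, with the annexin Anxa2 at 1.58 (SE 0.33), the proteoglycan Lum at 1.13 (SE 0.25), the collagen Col3a1 at 0.74 (SE 0.18) and the receptor Pdgfrb at 0.57 (SE 0.08). The median was 0.57, with an adjusted p of 1.1e-05 by camera, an adjusted p = 0.348 with an estimated correlation and 3.29e-06 to 5.17e-05 under its other settings, and an adjusted p of 0.0195 by fry. The number that rose was 3 without mutant replicate 4, 4 without control replicate 1 or 4 or mutant replicate 1 or 2, and 5 without control replicate 2 or 3. The Col3a1 call was lost without mutant replicate 1, 2 or 4 (adjusted p from 0.0502 to 0.0540).

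Of 11 bile duct and progenitor genes, 3 rose and 0 fell, and 4 rose adjusted over the list alone. These were Prom1 and the keratins Krt18 at 1.14 (SE 0.24) and Krt8 at 0.92 (SE 0.24), which hepatocytes also express. Krt7, at 0.81 (SE 0.26, adjusted p = 0.0577) from a control mean of 2.53, below the floor, did not pass. It passed without mutant replicate 1 (adjusted p = 0.0296) and under 2 other alternatives. The median was 0.81, with an adjusted p of 0.00507 by camera, an adjusted p = 0.348 with an estimated correlation and 0.00159 to 0.0150 under its other settings, and an adjusted p of 0.0193 by fry. The Krt8 call held only without control replicate 4 or mutant replicate 5 (adjusted p up to 0.0671 in the other 8 fits without 1 array).

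Sinusoidal and vascular endothelial genes had a median of -0.13, with 0 higher and 2, Lyve1 and Oit3, lower of 13, and the same counts adjusted over the list alone (camera adjusted p = 0.0824). This list was called without control replicate 1 (adjusted p = 0.0146), control replicate 4 (0.0349) or mutant replicate 2 (0.0406), within 0.0146 to 0.232 over the settings of camera with a preset correlation. Only 1 fell without control replicate 1, 3, 4 or 5 or mutant replicate 1, 3 or 4. Of 8 lymphocyte genes 1, Ptprc, rose and 0 fell, with 0 and 0 adjusted over the list alone, 2 at an unadjusted p under 0.05 by limma, and a median of 0.17 (camera adjusted p = 0.508), and 0 rose without any 1 array other than control replicate 5 and mutant replicates 3 and 5. Of 5 erythroid genes, 0 passed limma, adjusted over the list alone or unadjusted, at a median of -0.44 (camera adjusted p = 0.497).

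Interferon response genes were higher. Of 10 measured, 5 rose and 0 fell, and 7 rose adjusted over the list alone. The chemokine Cxcl10 rose by 1.91 (SE 0.54, adjusted p = 0.0361), Ifit1 by 1.69 (SE 0.47, adjusted p = 0.0345), the deubiquitinase Usp18 by 1.41 (SE 0.33, adjusted p = 0.0190) and Oas1a by 0.78 (SE 0.23, adjusted p = 0.0424). The median was 1.02, with an adjusted p of 0.000254 by camera, an adjusted p = 0.367 with an estimated correlation and 5.17e-05 to 0.00517 under its other settings, and an adjusted p of 0.0433 by fry. Only 1 member rose without control replicate 3, 4 or 5 or mutant replicate 4, 2 rose without control replicate 2, and 3 without control replicate 1 or mutant replicate 1. Calls were lost without control replicate 1, 3, 4 or 5 or mutant replicate 4 for Cxcl10, without control replicate 2, 3, 4 or 5 or mutant replicate 1 or 4 for Ifit1, and without any 1 array but mutant replicates 2 and 5 for Oas1a (adjusted p up to 0.0768, 0.0755 and 0.0925).

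The remaining lists were not called by camera. Cholesterol synthesis had the lowest median of these, -0.55, with 0 higher and 2, Pmvk and Ebp, lower of 20 (0 and 2 adjusted over the list alone) and an adjusted p of 0.0851. It was called without control replicate 1 (adjusted p = 0.0478), control replicate 4 (0.0324) or mutant replicate 1 (0.00274) and with the 75th percentile subtracted (0.0426), within 0.00274 to 0.533 over the settings of camera with a preset correlation. The number that fell was 0 without control replicate 3 or mutant replicate 2 and 1 without control replicate 2 or 5 or mutant replicate 3 or 4. Bile acid synthesis and transport genes gave 2 higher and 4 lower of 14 (2 and 4 adjusted over the list alone) and an adjusted p of 0.591. The higher count was 1 without control replicate 1 and 0 without control replicate 2, 3 or 5 or mutant replicate 1, 2, 3 or 4, and the lower count was 2 without control replicate 1, 2, 4 or 5 or mutant replicate 1 or 2. Cell cycle genes gave 2 higher, Ccnd1 and Ccne2, and 0 lower of 28 (1 and 0 adjusted over the list alone), with a median of -0.10 although camera placed the list upward (adjusted p = 0.801). Only 1 rose without control replicate 1, 2 or 5 or mutant replicate 1, 2, 3 or 4, and 1 fell without mutant replicate 5. Hepatocyte transcription factors gave 1 higher, Onecut2, and 0 lower of 17 (1 and 0 adjusted over the list alone, adjusted p = 0.107), and were called without control replicate 1 (adjusted p = 0.0478, within 0.0478 to 0.307 over the settings of camera with a preset correlation) and by fry (0.0378). In this list 2 rose without control replicate 1 or 5 and 4 without mutant replicate 5. Periportal genes gave 1 higher, Cdh1, and 0 lower of 8 (3 and 3 adjusted over the list alone, adjusted p = 0.651). Of these 0 rose without control replicate 1, 4 or 5 or mutant replicate 2, 3 or 4 and 2 without control replicate 3, and without mutant replicate 5 there were 2 higher and 2 lower. Urea cycle and amino acid breakdown gave 1 higher, Hpd, and 1 lower, Nags, of 12 (1 and 3 adjusted over the list alone, adjusted p = 0.651). There 1 rose without control replicate 1 or mutant replicate 5 and 0 without any other array, while 1 fell without mutant replicate 3, 4 without mutant replicate 5 and 0 without any other array.

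Fatty acid oxidation and ketogenesis genes gave 3 higher, Pdk4, Acot1 and Hadhb, and 1 lower, Acaa2, of 17 (3 and 1 adjusted over the list alone, adjusted p = 0.591), with a median of -0.03 and a mean of 0.17. The higher count was 0 without control replicate 1, 2 or 3 or mutant replicate 1 and 1 without control replicate 5 or mutant replicate 2 or 4. Glucose and glycogen metabolism gave 1 higher, Irs2, and 2 lower, Pklr and Gbe1, of 13 (3 and 2 adjusted over the list alone, adjusted p = 0.728). In that list 0 rose without control replicate 1, 2 or 4 or mutant replicate 1, 2 or 4 and 2 without mutant replicate 5, and 1 fell without control replicate 1, 3 or 4 or mutant replicate 1, 2 or 4. Among stress responses, the p53 target list gave 0 higher and 1 lower, Ei24, of 13 (3 and 2 adjusted over the list alone, adjusted p = 0.287), and 3 higher and 2 lower without mutant replicate 5. The integrated stress list gave 1 higher, Atf3, and 1 lower, Chac1, of 14 (0 and 1 adjusted over the list alone, adjusted p = 0.420), with 0 higher without control replicate 2, 3, 4 or 5 or mutant replicate 2 or 4, and 3 and 4 lower without control replicate 5 and mutant replicate 5. The oxidative stress list gave 1 higher, Gstm3, and 1 lower, Gclc, of 15 (0 and 1 adjusted over the list alone, adjusted p = 0.142), with 0 higher without any 1 array other than mutant replicate 5. The acute phase list gave 1 higher, Lcn2, and 1 lower, Apcs, of 14 (1 and 1 adjusted over the list alone, adjusted p = 0.650), and 2 lower without control replicate 4.

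In all, camera called 13 of the 29 lists with the preset correlation and 0 with estimated correlations, where 3 had an unadjusted p under 0.05, and the directional fry test called 12. Among 100 splits of the 10 arrays into groups of 5, 16 called at least 13 lists, the real split included, so chance is not excluded for the number of lists called. The splits other than the real one called a median of 8 lists, so a list call at the preset correlation is weak evidence alone.

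**Figure D4:**
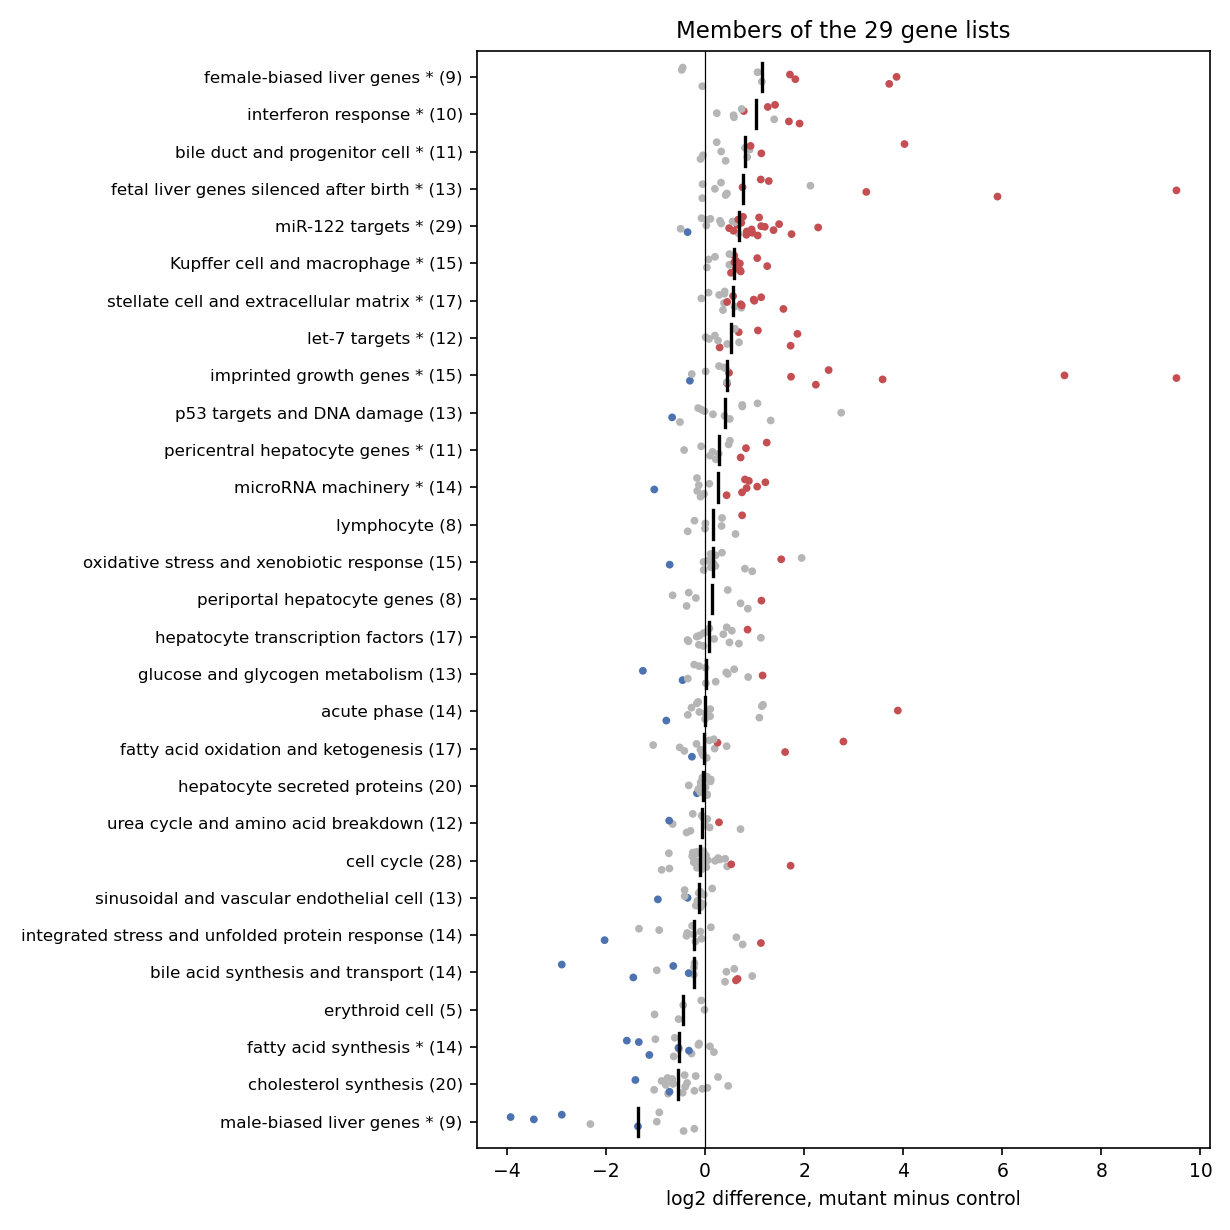
Difference of each measured member of 29 gene lists on the log2 scale (x axis), with the lists sorted by their median (black bar), the number measured in brackets and an asterisk for the 13 lists called by camera with a preset correlation. Members past the gene test are red where higher and blue where lower in mutants, and medians run from -1.36 for male-biased to 1.15 for female-biased genes.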

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

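The tests of the explanations for mutant replicate 5 were chosen after the result was seen. Within each group of 5 arrays, 72 genes picked by the naming rule and lists were searched for 1 array that stood apart from the other 4. The measure was the gap to its neighbour over the range of the group (threshold 0.71 for 5 arrays). Of 172 groups, 11 stood out, where chance, at about 1 in 20 groups, gives 8.60, and in 7 of the 11 the array was mutant replicate 5.

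Mutant replicate 5 lay nearer to the controls than the other 4 mutants for Afp (8.50 against 13.17 to 14.91), Igf2 (13.64 against 15.07 to 15.49), Igf2r (9.31 against 10.50 to 10.84), Meg3 (10.45 against 13.13 to 13.50), Plagl2 (5.77 against 6.69 to 6.86), Pls1 (7.37 against 9.57 to 10.13) and Ppm1m (7.62 against 5.03 to 5.76). In the other mutants, Lpl stood out in mutant replicate 2 at 13.71, against 13.35 to 13.43. Among controls, Cdkn1c stood out at 5.88 (6.07 to 6.11 in the others) and Krt7 at 2.82 (2.41 to 2.49) in control replicate 4, and Sox4 at 6.57 (7.51 to 7.76) in control replicate 1.

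Over 668 genes called without it, mutant replicate 5 reached a median share of 0.274 of the change in the other 4 mutants (quartiles 0.101 and 0.449), against medians of 0.916 to 1.28 for the others, each set against a mean that includes mutant replicate 5. A control liver carrying a mutant label is argued against by Dicer1, which lay -1.10 from the control mean on the less affected probe set, 9.13 control SDs below the lowest control. A smaller loss of the Dicer1 transcript is argued against by a share of its fall of 0.95 on 1 probe set and 1.09 on the other. Sex of the animal and other differences that the labels do not record stay open, since only 1 other mutant, replicate 2, was high in Xist (a median share of 1.14, against 0.307 for replicate 5, over 543 genes and the 3 mutants with Y-linked signal).

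Of 4345 probe sets that carry several gene symbols or none, 283 passed the test over all probe sets, 111 higher and 172 lower in mutants, and they lie outside the gene counts and lists.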

How the results depend on the processing

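The Xist covariate was chosen after the data were seen. Both Dicer1 probe sets kept direction and call under every alternative run. So did 50 of 72 genes under every alternative run on them. The 72 are those that the naming rule took as Dicer1, as the largest differences or from the called lists. Other genes in the text were not in this tally. For these 72 genes 121 calls were lost, 98 of them without 1 array, where fewer arrays were fitted, and 14 with the replicate block, and 3 were gained. For lists 23 calls were lost, 13 of them with estimated correlations, and 9 gained. Without 1 array, 627 to 1371 genes were higher and 764 to 2160 lower, 129 to 300 and 104 to 368 by at least 1. With dim genes left out, 128 were higher and 109 lower by at least 1, as fewer genes were tested. With all probe sets tested separately, 346 were higher by at least 1, and groups did not overlap for 865 lower genes. With estimated correlations, 0.0717 to 0.721 for the called lists against the preset 0.01, 0 lists were called by camera and 3 at an unadjusted p under 0.05. The replicate block gave 719 higher and 1117 lower genes, and 1597 of the 2488 calls were shared. Deviations of same-numbered arrays correlated between -0.183 and 0.0876, and 1 of 5 controls correlated best with its own number. No pairing by number was seen, but this cannot exclude shared litters or batches. Rescaling left 40.3% to 46.1% of calls higher, against 42.8%. With the most variable probe set, Gnas was 0.20 and Slc1a2 -0.39, which are other probe sets of these genes. Medians near 0 turned sign, for lists not called there. Fatty acid oxidation was 0.00847 with quantile normalization, 0.00053 without dim genes and -0.0664 to 0.0514 without 1 array. Cell cycle was 0.00358 without dim genes and -0.269 to 0.0459 without 1 array. Hepatocyte transcription factors were -0.0196 with the mean of probe sets and -0.0154 with the most variable one. Acute phase was -0.00811 with array weights and -0.0337 to 0.0526 without 1 array. Without 1 array, the urea cycle was -0.203 to 0.0237 and glucose metabolism -0.00437 to 0.0512. For these signs, the probe set and overlap counts, the cause was not tested. Seed site tests were not run, as untranslated sequences were not used here, nor were pseudocounts, as values were already logs. Signals near the floor, under 3.60, limit what a low gene can show.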

Other observations

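The gene families and the tests of this part were chosen after the data were seen, except the splits of the arrays. Of 76 mitochondrial ribosomal protein genes 44 fell and 0 rose, with a median of -0.43 (camera adjusted p = 0.174 with an estimated correlation). Of 43 genes for subunits and assembly factors of complex I, the NADH dehydrogenase, 23 fell and 0 rose (median -0.31), and of 17 ATP synthase genes 11 fell and 0 rose (median -0.40), each with an adjusted p = 0.176 with an estimated correlation. Among 21 genes of the import translocases 14 fell and 0 rose (median -0.43), and genes of complexes III and IV gave 5 lower of 8 and 7 lower of 13, with 0 higher in each. For each of these 3 families the adjusted p = 0.174 with an estimated correlation. Of 44 cytosolic ribosomal protein genes 24 fell and 0 rose, at a median of -0.24 (adjusted p = 0.174 with an estimated correlation), while 39 proteasome genes gave 5 higher and 2 lower and a median of -0.00584, whose sign turned under each of 3 rescalings. All other family medians kept their sign under these rescalings. Without 1 array, mitochondrial ribosomal genes gave 26 lower without control replicate 3 or mutant replicate 4 and 28 without control replicate 4 or mutant replicate 2. Complex I gave 13 without control replicate 3 or mutant replicate 2 or 4, 14 without control replicate 2 or mutant replicate 3 and 15 without mutant replicate 1. Complex IV gave 3 without control replicate 1, 2, 3 or 4 or mutant replicate 2 or 4 and 4 without control replicate 5 or mutant replicate 1, and ATP synthase gave 6 without control replicate 3 or mutant replicate 2 or 4 and 7 without control replicate 2. Proteasome genes gave 3 higher without mutant replicate 4 and 4 lower without mutant replicate 5, and without mutant replicate 5 there was also 1 higher ATP synthase gene and 1 higher cytosolic ribosomal gene.

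Another noncoding RNA of the imprinted Meg3 and Rian cluster, Mirg, rose by 3.04 (SE 0.70, adjusted p = 0.0185 by limma), and Airn, the noncoding RNA of the Igf2r locus, rose by 0.98 (SE 0.30, adjusted p = 0.0457). Both were chosen after their values were seen, and both control means, 3.50 and 4.27, lie near the floor.

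The fall of 178 mitochondrial genes together, at a median of -0.39 (camera adjusted p = 0.174 with an estimated correlation), was weighed against technical explanations. Normalization that depends on signal, as the whole cause, was set against 10000 random lists matched on mean signal. They had a typical median of -0.04 and a lowest of -0.16. Among genes at or above the median signal those of short genomic span were lower, with a median of -0.24 in the shortest of 10 bins and 0.11 in the longest. The 10000 lists matched on span and signal had a typical median of -0.12 and a lowest of -0.23, so span goes with part of the fall. All these lists were drawn gene by gene, while the mitochondrial genes vary together (estimated correlation 0.474). The lowest medians can therefore understate what such a set reaches. The typical medians, beside -0.39, argue against signal or span as the whole cause only as far as these genes count as independent. RNA quality stays open for part of the fall. The signal at the 3 prime minus the 5 prime end of Actb and Gapdh averaged 0.198 ± 0.0485 (SD, n = 5) in controls and 0.199 ± 0.0662 (SD, n = 5) in mutants. The slope of the fall on it within groups, -1.08 (95% interval -2.95 to 0.79), times the group difference gave -0.00105. The outer ends of the 95% intervals of slope and difference, multiplied, allow -0.25 of the -0.39, which is not itself a 95% limit. What else lowered these genes was not tested.

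By camera with a preset correlation the female-biased list, with 4 of 9 members called, was higher and the male-biased list, with 4 of 9 called, was lower, but the adjusted p = 0.367 and 0.348 with an estimated correlation, both calls were lost without dim genes (0.257 and 0.0890), and the female-biased call also by fry (0.0667) and without mutant replicate 5 (0.0664), within 0.00104 to 0.257 and 0.000734 to 0.0890 over the other settings of camera. Unequal numbers of females are argued against by the counts, since each group held 3 arrays with Y-linked signal and 2 with high Xist signal. Control replicate 4 and mutant replicate 3, among the former, also had some Xist signal. On the arrays with Y-linked signal the mean of the female-biased minus that of the male-biased list differed by 3.45. It ran from -3.61 to -3.39 in controls and from -0.18 to 0.07 in mutants. On the arrays with high Xist signal, 2 in each group, the means were -0.64 and 2.20, a difference of 2.84. Relative to the mean of all controls, the female-biased list there stood at 1.66 and 0.65 in controls and 1.70 and 2.28 in mutants. It thus hardly separated control replicate 2 from mutant replicate 2. The male-biased list stood at -0.54 and -0.61 in controls and -3.41 and -1.75 in mutants. A general loss of hepatocyte transcripts is argued against by 38 members of 5 hepatocyte lists, at a median of 0.118 (quartiles -0.12 and 0.53). The male-biased list had a median of -1.36. These members had control means up to 13.90, the highest of the male-biased list, and 18 secreted protein genes above it were left out. No lower bound was set, so dim members with little room to fall can be among them. The pericentral list, 1 of the 5, was itself called higher by camera with a preset correlation. What shifted the sex-biased lists was not tested and stays open.

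The number of genes called was set against other splits of the 10 arrays into groups of 5. Of 100 splits drawn from 126, 1, the real one, gave as many as 2488 genes, and the highest of the others gave 575. Chance is argued against for this count, but 1 in 100 is the smallest share that these splits can show. The split with 575 genes exchanged control replicate 1 and mutant replicate 5. For the 13 lists called, 16 of the 100 splits gave as many or more, up to 17, so chance is not excluded for the number of lists. The splits that called most lists each exchanged 1 control and 1 mutant. They keep part of the group difference, so their counts are not a plain measure of chance.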
